A study of Mus musculus with 24 samples.

How the data were processed

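Gene expression was measured in primary osteoblasts, the bone-forming cells, isolated from the calvaria (skull vault) of mouse pups aged 7 to 10 days and used at passage 2. Cells came from wild-type C57BL/6J mice and from mice lacking β-arrestin 2 (gene Arrb2), an adaptor protein that desensitises G protein-coupled receptors, on the same background. Per the labels, medium with 5 mM β-glycerophosphate and 50 mg/L ascorbic acid, which drives osteoblast differentiation, was given from day 3, so the day 2 cells had not yet received it. RNA was collected on days 2, 5, 10 and 28, and 100 ng per sample was hybridised to Affymetrix Mouse Gene 2.0 ST arrays. There were 8 groups of 3 arrays (2 genotypes by 4 days), 24 arrays in all. The labels describe the 3 replicates of a group as biological replicates prepared independently.

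The authors deposited log2 expression values, 1 per transcript cluster and array, made with RMA (background correction, quantile normalization and summarisation of the probes) in Affymetrix Expression Console, per the submitters' processing notes. Software versions and the array library build are not given in the sources used here. The values were used as deposited and ranged from 0.313 to 14.08 on the log2 scale. RMA makes the arrays share 1 distribution over probes, so a shift common to most genes would be removed. Array medians lay between 4.55 and 4.72, and among the contrasts the median change over the tested genes farthest from 0 was -0.037. No 2 columns were identical (0 pairs), and 0 columns of the table were left unused. Depth is not a property of array values, and the number of arrays limits the precision.

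Of the 41345 transcript clusters, 25335 had a gene in the platform annotation. Of these, 23521 had exactly 1 symbol and 1814 had several, while 16010 clusters had no listed gene. A further gene table, of assembly GRCm38.p6, was matched by gene identifier for 23328 of the single-symbol clusters and was used only for current symbols and for the order of neighbouring genes. Only single-symbol clusters were named. For the 1082 genes with more than 1 cluster, the cluster with the highest mean over all arrays was kept, which gave 22180 genes. A gene was tested when it reached the median of its array in at least 3 of the 24 arrays, which left 14892 genes. Spp1 and Runx2, both usual osteoblast markers, were not represented by a single-gene cluster and are not analysed here.

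A linear model with 1 mean per genotype and day was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual and 4 prior degrees of freedom), so that all groups shared 1 estimate of the spread. It gave 15 tests: days 5, 10 and 28 against day 2 in each genotype, knockout against wild type at each day and as the mean over days, the difference of the changes between genotypes at days 5, 10 and 28, and an F test over these 3 differences. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each test, and genes with an adjusted p under 0.05 are called changed. Every adjusted p of a gene is from limma. Gene lists, 34 in number, for stages of the bone cell, other cell types, matrix, signalling and metabolism, were fixed before the data were examined and tested with camera, limma's competitive set test, with a preset correlation of 0.01 between genes and adjustment over the lists of a contrast. The same test with a correlation estimated from the residuals, and fry, limma's self-contained set test, were run beside it. For each list the members past the threshold were also counted after adjustment over the list alone.

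The genes named were chosen by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap between the groups (for the mean over days, the same sign at all 4 days; no overlap condition for the differences of changes), leaving out symbols of predicted or unnamed genes. From each list described it took up to 4 members with the largest change past the threshold, or 2 where none passed. It always allowed Arrb2, Arrb1, Alpl, Bglap, Ibsp, Spp1, Sp7, Runx2, Col1a1, Dmp1, Sost and Pth1r. Any feature named outside this rule is marked as such.

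Replicate numbers in the labels recur in every group. Whether they pair arrays was checked from the correlation of the arrays' deviations from their group means, before calls were compared. Every same-numbered pair exceeded 0.1 for day 5 against day 2 in the wild type (0.25, 0.26 and 0.35) and in the knockout (0.20, 0.41 and 0.15), and for day 10 (0.15, 0.33 and 0.24) and day 28 (0.17, 0.16 and 0.10) against day 2 in the knockout, where the value for the third pair of day 28 lay just above the limit. The pairing therefore comes from the data, within a genotype. The limit was not met for days 10 and 28 of the wild type (lowest pair 0.08 and 0.05) or between the genotypes. Sex-linked genes still followed the number in the labelled wild type. Xist was at 3.56 to 4.31 on replicate 2 over the 4 days. Eif2s3y was at 3.80, 3.46 and 3.68 on replicate 3 of days 2, 10 and 28. It was at 5.94 on replicate 3 of day 5, so the pairing of that array with day 2 is less sure. Some same-numbered arrays of the 2 genotypes shared deviations too. The pairs were at 0.33, 0 and 0.52 on day 2 and at -0.08, 0.08 and 0.14 on day 5. They were at -0.01, 0.25 and 0.37 on day 10 and at -0.01, 0.25 and 0.26 on day 28. A structure shared by number across the genotypes is thus not excluded. Below, the arrays sharing a genotype and a replicate number are called a preparation, although the labels do not say that the same cells were followed over the days.

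Alternatives were no filter or a stricter filter (75th percentile) on dim genes, all transcript clusters, cyclic loess, a trended robust prior, array weights, the replicate number as a block (fixed or random), only the 2 groups compared, and leaving out each array in turn. Leaving out each of the 3 preparations of a genotype, covariates for sex-linked genes and preparation means were added after the data had been seen, as was a comparison of each called gene's values with the array medians. Other splits of the samples, up to 100 per test, were refitted. The steps were tested on simulated data with known changes. Simulated values were drawn independently with each gene's residual spread, without preparation effects or correlation between genes. The real arrays show structure by preparation, so the shares called may be too high for them. In simulations of 14892 genes for knockout against wild type at day 28, 12.1%, 76.1% and 92.5% of genes changed by 0.5, 1 and 2 on the log2 scale were called. For the difference of changes at day 28 these shares were 3.03%, 44.8% and 88.1%, and for day 28 against day 2 in the knockout 19.7%, 79.1% and 94.0%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.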

Results

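Calvarial osteoblasts from wild-type mice and from mice lacking β-arrestin 2 were followed through 28 days of culture, with 3 arrays for each genotype on days 2, 5, 10 and 28. Time explained most of the variation. The first principal component of the 14892 tested genes carried 57.6% of the variance and the second 8.52%. Arrays of a group correlated with each other at 0.970 to 0.984, and arrays of different groups at 0.937 to 0.985. Expression values are log2 RMA values deposited by the authors, given as mean ± SD over 3 arrays, and changes are differences of log2 means from limma. No detection call was used, so where all 3 values of a compared group lay below the medians of their arrays the size and rank of a difference are uncertain. This held for 40 of 826, 324 of 4568 and 528 of 5774 called genes in the labelled wild type (days 5, 10 and 28 against day 2). In the labelled knockout it held for 20 of 412, 203 of 3665 and 476 of 5658, and between genotypes for 1 of 5 on day 10 and 2 of 34 on day 28. Genes concerned are given with each comparison only where the text mentions them.

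The targeted gene was examined first. Arrb2 signal was higher, not lower, in the arrays labelled knockout. It was 7.09 ± 0.29 against 5.88 ± 0.13 on day 2 (n = 3 each, 2.31-fold higher, limma adjusted p = 0.0206) and 6.69 ± 0.09 against 5.11 ± 0.10 on day 5 (2.99-fold higher, adjusted p = 0.000357). On day 10 the means were 6.62 ± 0.17 and 5.80 ± 0.27, and on day 28 they were 6.85 ± 0.24 and 6.44 ± 0.33. Neither of these later differences passed the test (log2 differences 0.82 and 0.40, adjusted p = 0.0932 and 0.797). The gap also moved with the labelled wild type, where Arrb2 was called lower on day 5 and higher on day 28 than on day 2. Each of these 2 calls was lost in 2 fits that left out an array (limma adjusted p up to 0.0612 and 0.122). All 3 arrays labelled knockout lay above all 3 labelled wild type on days 2, 5 and 10, and 1 of 3 did on day 28. Over the mean of the days the difference was 1.00 (adjusted p = 6.44e-06). That p treats the days of a preparation as independent. Arrb2 was still called with a random replicate block, but not in limma on the means of the 3 preparations per genotype, which called no gene. The signal therefore goes against the genotype labels, and every direction below is that of the arrays as labelled. Which part of the gene was deleted, and where the probes lie relative to it, are not given in the sources used here, and probes outside a deleted part check nothing. Arrb1, the related β-arrestin 1, did not differ past the threshold on any day (log2 differences 0.10, 0.15, -0.05 and 0.29). The call for Arrb2 on day 2 ended without replicate 2 of the day 2 knockout (adjusted p = 0.175) and in 4 of the 6 fits that left out an array.

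**Figure D1:**
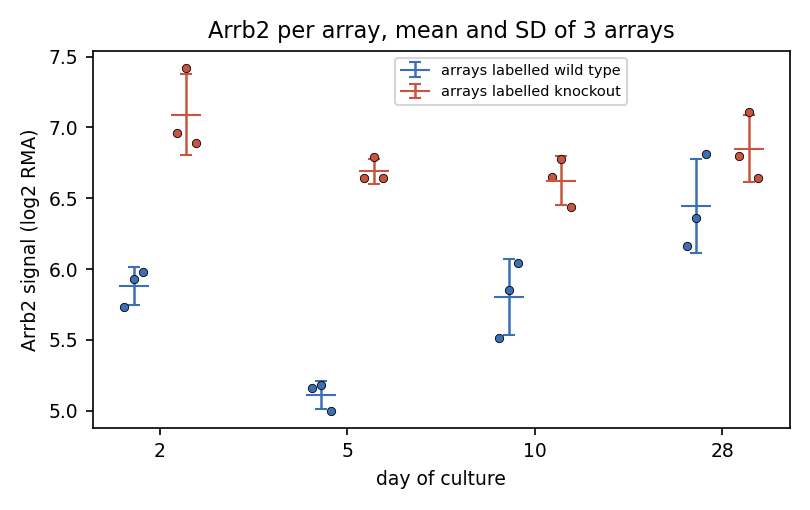
Arrb2 signal (log2 RMA, vertical axis) on each of the 24 arrays by day of culture, with mean and SD of 3 arrays per group. The arrays labelled knockout lie above those labelled wild type on days 2, 5 and 10, and the groups overlap on day 28.

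Between day 2 and day 5, the first interval that includes differentiation medium, the largest rise in the cells labelled wild type was in Mmp13 and the largest fall in Slc7a3, and 11 of 24 genes of the unfolded protein and amino acid response fell. Mmp13, which encodes the collagenase of bone and cartilage remodelling, rose from 7.38 ± 1.75 to 12.15 ± 0.44 (n = 3 each, log2 change 4.77, limma adjusted p = 0.000727). The collagen-binding proteoglycan gene Lum (3.50, adjusted p = 0.00145), dermatopontin (Dpt, 3.43), hepatocyte growth factor (Hgf, 3.25, adjusted p = 1.16e-05) and angiopoietin 1 (Angpt1, 3.24) rose as well, as did Apod (3.47) and Serpinb1a (3.39). The cationic amino acid transporter gene Slc7a3 fell most (-3.93, adjusted p = 1.05e-06), followed by Rasgrp3 (-3.40), the cartilage proteoglycan gene Acan (-3.24), Cth, which makes cysteine (-3.16, adjusted p = 4.67e-09), the cystine transporter Slc7a11 (-3.13), Cdsn (-2.94), Ostn (-2.82) and Car6 (-2.63). In all, 425 genes rose and 401 fell, 826 of 14892, of which 291 changed at least 2-fold. The day 5 values of Ostn and Car6 lay below the array medians. Of 18 matrix protease genes 6 rose and 2 fell (9 over the list alone, median 0.33, camera adjusted p = 0.0166, adjusted p = 0.513 with an estimated correlation), and of 28 fibrillar matrix genes 4 rose and 1 fell, with no shift of the list (7 over the list alone, median 0.04, adjusted p = 0.355).

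Of 24 genes of the unfolded protein and amino acid response, 11 fell and none rose (0, 15 called when adjusted over the list alone, median -0.95, camera adjusted p = 8.78e-14). The fallers included Slc7a11, the amino acid transporter Slc7a5 (-2.52), the stress pseudokinase Trib3 (-2.30) and the glutathione-degrading Chac1 (-1.92). Among 24 BMP and TGF-β target genes, 10 fell (13 over the list alone, median -0.58, adjusted p = 1.38e-06), among them the inhibitory Smads Smad7 (-1.49) and Smad6 (-1.40), the BMP antagonist Nog (-1.28) and Ccn2 (-1.22). These lists were called with an estimated correlation too (adjusted p = 0.0381 for both), but not with the replicate block (adjusted p = 0.0899 for both with an estimated correlation). All 19 genes of cholesterol synthesis had positive changes (median 1.02, adjusted p = 1.33e-13) and 9 rose, including Insig1 (1.44), Nsdhl (1.35), Hmgcs1 (1.33) and Pmvk (1.15); 17 were called when adjusted over the list alone. The call of that list was lost with estimation of the correlation (adjusted p = 0.481 with an estimated correlation). Of 28 interferon-stimulated genes 4 rose, Rtp4 (2.94), Irf9 (1.83), Ifih1 (1.80) and Ddx58 (1.11), and 13 did when adjusted over the list alone (median 1.10, adjusted p = 3.15e-08, adjusted p = 0.648 with an estimated correlation). The mean of this list was 7.80, 6.87 and 5.52 on the 3 day 5 arrays against 5.26 to 5.56 on day 2, and all 4 genes lost their calls without any array other than replicate 3 of day 5 (Rtp4 up to adjusted p = 0.281).

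Bone markers moved little in this interval. No gene of the 13 early osteoblast genes passed (0 called, median 0.02, mean -0.18, camera direction down, adjusted p = 0.841). Alpl (alkaline phosphatase) changed by 0.16 (adjusted p = 0.947), Col1a1 by 0.15 and Ibsp (bone sialoprotein) by 0.70 (adjusted p = 0.851), with none past the test. Sp7 (osterix, -1.44) had an adjusted p of 0.173, or 0.0443 with the replicate block. Of 16 late osteoblast genes only Mgp rose (1.54, adjusted p = 0.00201; 1 over the list alone), and this list did not shift (median -0.08, mean 0.03, direction up, adjusted p = 0.841). Of 19 periosteal and suture progenitor genes, 5 rose, among them Cd34 (2.20) and Pdgfra (1.76), and 8 over the list alone (median 0.31, camera adjusted p = 0.0449, adjusted p = 0.514 with an estimated correlation and 0.0918 with the replicate block). The replicate block raised the count of called genes from 826 to 1366. Leaving out replicate 1 or 2 of day 2 gave 530 and 370, and replicate 1 or 2 of day 5 gave 377 and 355. The call of Insig1 was lost without any array except replicate 3 of day 5 (adjusted p up to 0.193), and that of Acan without replicate 1 or 3 of day 2 or replicate 1 or 2 of day 5 (up to 0.102). Nog lost its call without replicate 1 of day 2 or replicate 1 or 2 of day 5 (up to 0.0654), Nsdhl and Pmvk without replicate 1 of day 5 (0.0519 and 0.0501), and Cd34 and Pdgfra without replicate 2 of day 5 (0.0573 and 0.0568).

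By day 10, 18 of 21 adipocyte, 8 of 11 complement and 12 of 28 macrophage genes had risen in the cells labelled wild type, and 28 of 33 cell cycle genes had fallen. The largest rises over day 2 were in Egfl6 (7.64, adjusted p = 5.55e-06), the secreted Wnt modulator Sfrp2 (6.51), Pi15 (6.44), the fatty acid-binding protein gene Fabp4 (4.67 ± 0.80 to 10.67 ± 1.8; log2 change 6.01, adjusted p = 8.77e-06), Apod (5.82), Olfml1 (5.81), Dpt (5.71) and the metalloreductase gene Steap4 (5.68, adjusted p = 4.66e-10). The largest falls were in Ptgs2, the inducible cyclooxygenase (-5.03, adjusted p = 3.79e-06), Slc7a3 (-4.69), Slc7a11 (-4.63), Acan (-4.60), Gzmd (-4.08), Cdsn (-3.92), Slc7a5 (-3.71) and Cth (-3.69). In limma 4568 genes passed, 2151 higher and 2417 lower, and 1638 changed at least 2-fold. Of the genes named for this interval, Pi15, Olfml1, Steap4, Cd36, Mrc1 and Phex lay below the array medians on day 2, and Slc7a3, Slc7a11 and Gzmd on day 10.

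Of 21 adipocyte genes 18 rose by day 10 (20 over the list alone, median 1.32, camera adjusted p = 7.97e-10, adjusted p = 0.395 with an estimated correlation). They were led by Fabp4, Cd36, the fatty acid translocase (5.33), Lpl, lipoprotein lipase (5.05), and Car3 (4.75). Car3 is also among the late osteoblast genes, although it is best known as a carbonic anhydrase of fat and muscle. Of 11 complement genes 8 rose (9 over the list alone, median 2.19, adjusted p = 8.59e-06, adjusted p = 0.395 with an estimated correlation), with Serping1, the C1 inhibitor (5.09), C4b (3.34) and Cfb (3.21) among them. Of 28 macrophage genes 12 rose (14 over the list alone, median 1.56, adjusted p = 3.01e-05, adjusted p = 0.639 with an estimated correlation), led by the lysozyme gene Lyz2 (4.38), the mannose receptor gene Mrc1 (4.29) and cathepsin S (Ctss, 3.50). Interferon-stimulated genes rose in 14 of 28 cases (16 over the list alone, median 1.44, adjusted p = 8.59e-06, adjusted p = 0.639 with an estimated correlation), as with Ifit1 (3.78). All 33 cell cycle genes had negative changes and 28 fell (29 over the list alone, median -1.17, adjusted p = 7e-10, adjusted p = 0.483 with an estimated correlation), including Aurka (-1.89), Rrm2 (-1.83) and Hells (-1.75). The amino acid response list stayed low, with 16 of 24 lower than on day 2 (18 over the list alone, median -1.10, adjusted p = 7e-10, adjusted p = 0.176 with an estimated correlation). Of 18 smooth muscle and myofibroblast genes 11 fell and 1 rose (13 over the list alone, median -0.78, adjusted p = 0.000526, adjusted p = 0.424 with an estimated correlation), such as Actg2 (-2.19), Cnn1 (-1.84) and Tagln (-1.55).

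Among the Wnt genes, which include both agonists and antagonists, 9 of 32 rose and 5 fell by day 10 (15 over the list alone), with Sfrp2, the R-spondin receptor gene Lgr5 (4.78), Sfrp1 (4.61) and Rspo2 (4.49) at the top. The list as a whole did not pass (median 0.20, camera adjusted p = 0.0624). The late osteoblast list did not pass either (median 0.41, adjusted p = 0.28). In it Car3, Omd (3.13) and Mgp (1.80) rose and the phosphate transporter Slc20a1 fell (-3.37), 4 up and 1 down of 16 (5 over the list alone). Phex rose (3.25, adjusted p = 0.00549), Sp7 fell (-1.83, adjusted p = 0.023), and Ibsp (1.56, adjusted p = 0.427), Alpl (1.07), Dmp1 (1.11) and Bglap (-0.08) did not pass. The Sp7 call was lost without replicate 1 or 3 of day 2 or replicate 1 or 2 of day 10 (adjusted p up to 0.0779).

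On day 28 Ibsp, Bglap and Phex had risen, least on replicate 2, and 20 of 21 adipocyte, 11 of 11 complement and 25 of 28 macrophage genes had risen. Ibsp rose from 4.30 ± 0.66 to 9.43 ± 3.2 (n = 3 each, log2 change 5.12, limma adjusted p = 0.00552), Bglap (osteocalcin) rose by 1.35 (adjusted p = 0.00669) and Phex by 4.17 (adjusted p = 0.000535). On the 3 day 28 arrays Ibsp was at 10.65, 5.77 and 11.85, Bglap at 6.25, 4.76 and 6.24, and the late osteoblast list mean at 8.24, 7.23 and 8.98. Sp7 was lower than on day 2 (-1.55, adjusted p = 0.0428). Dmp1 (1.84, adjusted p = 0.0531), Alpl (1.19, adjusted p = 0.242), Col1a1 (0.16), Sost (0.06) and Pth1r (0.40) did not pass. The largest rises were in Car3 (7.84, adjusted p = 1.14e-06), Egfl6 (7.56), Fabp4 (7.49), Cd36 (7.22), Sfrp2 (6.66), Dpt (6.61), Apod (6.51) and Serping1 (6.30). The largest falls were in Ptgs2 (-5.91, adjusted p = 2.72e-07), Acan (-4.87), Slc7a3 (-4.52), Sema3e (-4.31), Gzmd (-4.03), Rgs4, which restrains G protein signalling (-3.90), Hbegf (-3.87) and Cdsn (-3.84). There were 5774 called genes, 2912 higher and 2862 lower, and 2250 changed at least 2-fold. Cd36, Mrc1, Lyz1, Phex, Bglap and Orm1 lay below the array medians on day 2, and Slc7a3 and Gzmd on day 28.

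Adipocyte genes rose in 20 of 21 cases by day 28 (20 over the list alone, median 2.91, camera adjusted p = 2.42e-16, adjusted p = 0.221 with an estimated correlation). Macrophage genes rose in 25 of 28 (26 over the list alone, median 3.21, adjusted p = 2.9e-09, adjusted p = 0.477 with an estimated correlation), with Mrc1 at 5.77, Lyz1 at 5.54 and Ctss at 5.47. All 11 complement genes rose (11 over the list alone, median 3.08, adjusted p = 8.87e-08, adjusted p = 0.256 with an estimated correlation). The interferon list had 19 of 28 higher (21 over the list alone, median 1.85, adjusted p = 6.15e-06, adjusted p = 0.515 with an estimated correlation). All 33 cell cycle genes fell (33 over the list alone, median -1.53, adjusted p = 4.43e-12, adjusted p = 0.451 with an estimated correlation), for example Rrm2 (-2.30) and Bub1 (-2.21). Of 16 late osteoblast genes 7 rose and Slc20a1 fell (9 called over the list alone, median 1.04, adjusted p = 0.0146, adjusted p = 0.477 with an estimated correlation). Besides Ibsp, the risers with the largest changes were Car3 and Omd (3.88). None of the 13 early osteoblast genes rose (0), and Msx2 (-2.91), Sp7, Atf4 (-1.18) and Dlx6 (-0.74) fell, with no shift of the list (3 over the list alone, median 0.10, mean -0.26, direction down, adjusted p = 0.704). In the osteocyte list Phex and Orm1 (2.61), the latter an acute phase protein of liver, were among 3 risers of 14, and the osteoprotegerin gene Tnfrsf11b (-2.76) and Cd44 (-1.60) fell (6 over the list alone, median 0.14, adjusted p = 0.625). The Sp7 call was lost without any array except replicate 3 of day 28 (adjusted p up to 0.209), and that of Dlx6 without replicate 1 of day 28 (adjusted p = 0.0908).

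**Figure D2:**
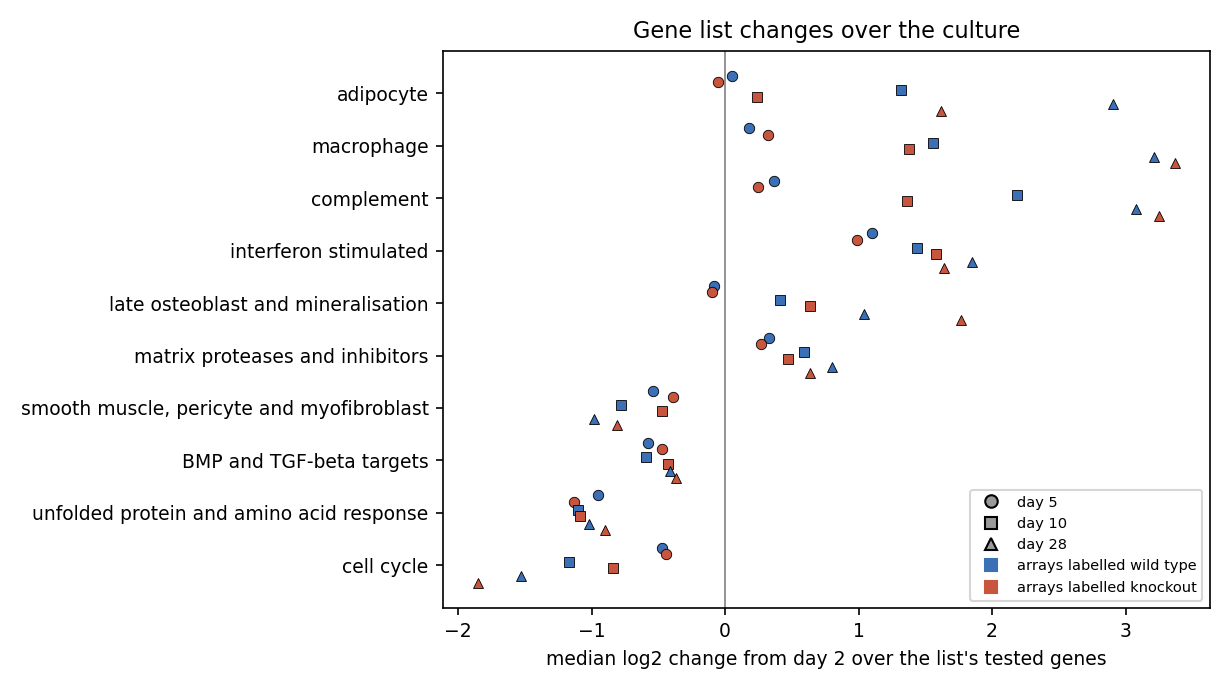
Median log2 change from day 2 (horizontal axis) of 10 gene lists on days 5, 10 and 28, for the arrays labelled wild type and those labelled knockout. The macrophage list reaches 3.21 and 3.37 on day 28, and the adipocyte list reaches 2.91 in the arrays labelled wild type and 1.62 in those labelled knockout.

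In the cells labelled knockout Mmp13 and Slc7a3 again had the largest rise and fall of the first interval. Mmp13 rose from 7.88 ± 1.6 to 11.46 ± 0.83 (n = 3 each, log2 change 3.57, limma adjusted p = 0.0111). Rises were also seen in Lum (2.63), Dpt (2.43), Angpt1 (2.21, adjusted p = 0.00316), the transcription factor gene Etv1 (2.19, adjusted p = 0.000403), the phosphodiesterase gene Pde7b (2.17), Serpinb1a (2.16) and AW551984 (2.15). The falls were led by Slc7a3 (-3.73, adjusted p = 2.6e-06), Slc7a11 (-3.47), Cth (-3.05, adjusted p = 9.05e-09), Rasgrp3 (-2.58), Ostn (-2.44), Trib3 (-2.38), Car6 (-2.38) and Slc7a5 (-2.35). In all 229 genes rose and 183 fell, 412 together, 163 of them at least 2-fold. Ostn lay below the array medians on day 5. Of 24 amino acid response genes 13 fell (15 over the list alone, median -1.13, camera adjusted p = 5.29e-19) and of 24 BMP and TGF-β genes 7 fell (10 over the list alone, median -0.47, adjusted p = 1.81e-06), again including Smad7 (-1.36) and Nog (-1.33). Both were called with an estimated correlation (adjusted p = 0.0122 and 0.041), but not with the replicate block added (adjusted p = 0.0938 and 0.1). All 19 cholesterol genes had positive changes, but none passed over all genes (0; 10 over the list alone, median 0.67, adjusted p = 1.95e-09, adjusted p = 0.6 with an estimated correlation). Nsdhl, at 0.99, had an adjusted p of 0.0675, or 0.0435 with the replicate block. All 28 interferon genes were positive too, with 1 riser, Ddx58 (1.14; 3 over the list alone, median 0.99, adjusted p = 4.86e-08, adjusted p = 0.6 with an estimated correlation), and the list mean was 5.68, 7.58 and 6.50 on the 3 day 5 arrays. No adipocyte gene passed (0 of 21; median -0.05, adjusted p = 0.818), and Pparg, at -1.24, had an adjusted p of 0.11, or 0.0441 with the replicate block.

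The replicate block raised the knockout day 5 count from 412 to 695. Without replicate 2 or 3 of day 2 the count was 176 and 230, and without replicate 2 or 3 of day 5 it was 227 and 124. Single arrays ended the calls of Mmp13 (day 2 replicate 1 or day 5 replicate 3, adjusted p up to 0.0765), Lum (up to 0.119), Dpt (up to 0.124), Serpinb1a (up to 0.107), AW551984 (up to 0.107), Ddx58 (up to 0.179) and Nog (up to 0.0913), the last 6 without replicate 2 or 3 of day 5 among others.

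On day 10 Sfrp2 had the largest rise in the cells labelled knockout, and 2 of 21 adipocyte genes rose. Sfrp2 (5.22, limma adjusted p = 2.14e-05), Egfl6 (5.19), Pgm5 (5.17), the enkephalin precursor gene Penk (5.14, adjusted p = 3.05e-07), Olfml1 (5.03), the matrilin gene Matn4 (4.78), Lgr5 (4.69) and Dpt (4.61) rose most. Slc7a3 (-4.43), Cth (-3.97, adjusted p = 6.24e-11), Ptgs2 (-3.91), Acan (-3.90), Slc7a11 (-3.87), Gzmd (-3.78), Rasgrp3 (-3.63) and Avil (-3.38) fell most. Olfml1 lay below the array medians on day 2, and Slc7a3 and Gzmd on day 10. Of 21 adipocyte genes, Lpl (2.76) and Cebpa (1.65) rose and Dgat2 fell (-0.90) (3 over the list alone, median 0.24, camera adjusted p = 0.173). The macrophage list shifted by a median of 1.38 (adjusted p = 0.000113, adjusted p = 0.732 with an estimated correlation), with 3 risers of 28, Lyz2 (2.77), Mrc1 (2.74) and Mpeg1 (2.44), and 1 over the list alone. Its mean was 8.10 on replicate 2 and 5.52 and 5.15 on the others, and without that array no call remained among these 3 (adjusted p = 0.0715, 0.261 and 0.314). That of Dgat2 was lost without replicate 3 of day 10 (0.0723) or replicate 2 or 3 of day 2. Complement genes rose in 6 of 11 cases (7 over the list alone, median 1.36, adjusted p = 0.000101, adjusted p = 0.456 with an estimated correlation). Interferon genes rose in 15 of 28 (20 over the list alone, median 1.58, adjusted p = 1.05e-07, adjusted p = 0.626 with an estimated correlation). Both lists were also highest on replicate 2 (list means 8.0 and 8.09).

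Cell cycle genes fell in 15 of 33 cases (28 over the list alone, median -0.84, adjusted p = 1.46e-07, adjusted p = 0.626 with an estimated correlation). Amino acid response genes fell in 15 of 24 (18 over the list alone, median -1.09, adjusted p = 4.57e-11, adjusted p = 0.115 with an estimated correlation). Of the Wnt genes 9 rose and 4 fell (14 over the list alone, median 0.22, adjusted p = 0.0315, adjusted p = 0.626 with an estimated correlation). The skeletal myosin genes Myh8 (3.23, adjusted p = 9.59e-05) and Myh1 (2.13, adjusted p = 0.00608) rose, the call of Myh1 being lost without replicate 3 of day 2 (adjusted p = 0.0521). Ibsp (2.73, adjusted p = 0.158), Alpl (2.08, adjusted p = 0.0557) and Col1a1 (0.49, adjusted p = 0.0864) passed with the replicate block (adjusted p = 0.0384, 0.00302 and 0.0181). Ibsp was at 5.12, 5.60 and 11.33 on the 3 day 10 arrays, so its change rests mainly on replicate 3, and the late osteoblast list mean was 6.72, 6.89 and 8.11. Past the test with the block was also the change in Arrb2 (-0.47, adjusted p = 0.06, or 0.0142 with the block). There were 3665 called genes, 1647 higher and 2018 lower, 1106 at least 2-fold, and 2396 without replicate 3 of day 2.

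By day 28 Ibsp, Dmp1, Alpl, Bglap and Phex had risen in the cells labelled knockout. Ibsp went from 4.62 ± 0.61 to 11.06 ± 1.5 (n = 3 each, log2 change 6.44, limma adjusted p = 0.000955). Dmp1, an osteocyte matrix protein gene, rose by 2.98 (adjusted p = 0.00317), Alpl by 2.12 (adjusted p = 0.0358), Bglap by 1.82 (adjusted p = 0.000632) and Phex by 4.65 (adjusted p = 0.000206). Replicate 2 was the lowest of the 3 day 28 arrays for each of them, with Ibsp at 9.52, Bglap at 5.37 and Alpl at 7.17, the last below its value of 7.30 on replicate 2 of day 2. On day 2 Dmp1, Phex, Cd36 and Steap4 lay below the array medians and Bglap lay near them (4.61, 4.53 and 4.53), and Gzmd lay below them on day 28. The largest rises were in Car3 (7.03, adjusted p = 5.77e-06), Ibsp, Fabp4 (6.12), Egfl6 (6.08), Steap4 (5.96), Cd36 (5.93), Sfrp2 (5.90) and Dpt (5.84). The largest falls were in Ptgs2 (-5.66, adjusted p = 7.12e-07), Sema3e (-4.34), Cth (-4.09), Acan (-3.72), Slc7a3 (-3.71), Gzmd (-3.66), Hbegf (-3.60) and Slc20a1 (-3.50). Called genes numbered 5658, 2884 higher and 2774 lower, 2197 at least 2-fold. The call of Alpl was lost without replicate 1 of day 2 or replicate 1 or 3 of day 28 (adjusted p up to 0.202). Pth1r, the parathyroid hormone receptor gene, changed by 0.86 (adjusted p = 0.0774, or 0.004 with the replicate block).

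Late osteoblast genes rose in 10 of 16 cases and 1 fell (11 over the list alone, median 1.77, camera adjusted p = 0.00165, adjusted p = 0.389 with an estimated correlation). Of 13 early osteoblast genes 4 rose and 2 fell, with Dlx3 up (1.69; adjusted p = 0.0531 without replicate 3 of day 28) and Msx2 down (-2.61), and the list did not shift (6 over the list alone, median 0.27, adjusted p = 0.496). Adipocyte genes rose in 18 of 21 cases (19 over the list alone, median 1.62, adjusted p = 7.51e-09, adjusted p = 0.337 with an estimated correlation). So did macrophage genes in 26 of 28 (26 over the list alone, median 3.37, adjusted p = 8.46e-11, adjusted p = 0.389 with an estimated correlation) and complement genes in 11 of 11 (11 over the list alone, median 3.25, adjusted p = 3.1e-07, adjusted p = 0.337 with an estimated correlation). The macrophage mean was 8.13, 9.86 and 6.60 on the 3 arrays, and the early osteoblast mean was 9.37, 8.43 and 9.81. Cell cycle genes fell in 32 of 33 cases (32 over the list alone, median -1.85, adjusted p = 2.95e-16, adjusted p = 0.389 with an estimated correlation). In the cholesterol list 7 of 19 fell, among them Fdps (-1.12) and Cyp51 (-1.08) (7 over the list alone, median -0.48, adjusted p = 0.0514, or 0.0441 with the replicate block), a call not held with an estimated correlation (adjusted p = 0.744, or 0.685 with the block). Myh8 (2.69) and Myh1 (2.65) were higher than on day 2, while 7 other genes of the 21 in the skeletal muscle list fell (9 over the list alone, median -0.33, adjusted p = 0.0811).

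The courses of the 2 genotypes ran closely together. Across 14892 genes the changes from day 2 correlated at Pearson r = 0.823 on day 5, 0.906 on day 10 and 0.947 on day 28 (Spearman rho 0.691, 0.829 and 0.903), a description across genes, which are not independent replicates, from arrays not shared between the genotypes. The slope of the knockout changes on the wild-type changes was 0.704, 0.766 and 0.906. Noise in the wild-type changes lowers such a slope, so these values alone do not show weaker changes in the knockout. Both genotypes called 315, 2915 and 4626 genes in the same direction and 0, 3 and 0 in opposite directions. Independent lists of these lengths would share 7 higher and 5 lower genes on day 5, 238 and 328 on day 10, and 564 and 533 on day 28.

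**Figure D3:**
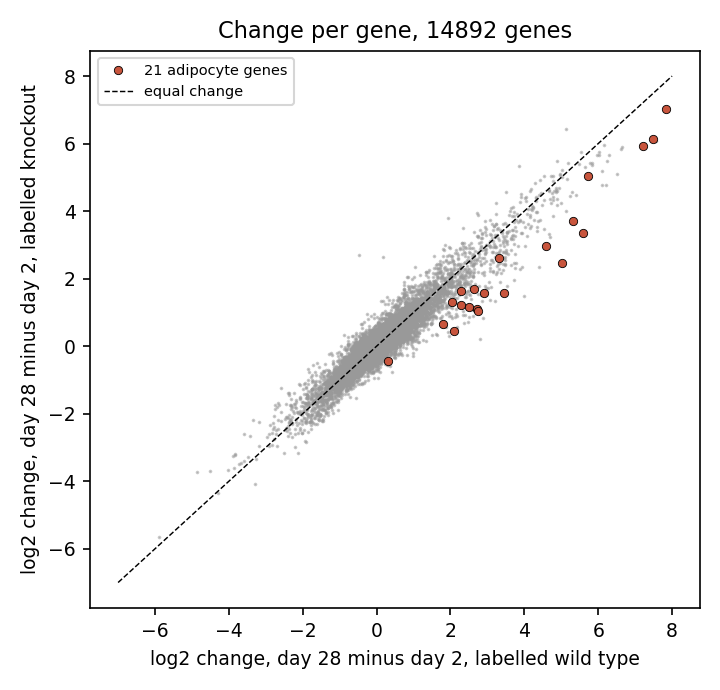
Log2 change from day 2 to day 28 per gene in the arrays labelled knockout (vertical axis) against that in the arrays labelled wild type (horizontal axis), for 14892 genes, with the 21 adipocyte genes marked and a line of equal change. The adipocyte genes lie below the line, at a median of 1.62 against 2.91.

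Few differences between knockout and wild type as labelled passed the test early. Arrb2 itself was the only gene called on day 2 (1 gene; 212 at an unadjusted p under 0.05) and the only gene called on day 5 (1 gene; 396 at an unadjusted p under 0.05), each time higher in the arrays labelled knockout. Both unadjusted counts lie below what chance alone would give among 14892 genes, so real differences may have been missed. Of the clusters without a single gene name, 3 were called on each of these days and are described further below. Alpl (log2 differences -0.20 and 0.32), Ibsp (0.32 and -0.21), Sp7 (-0.08 and 0.64), Bglap (0.15 and -0.12), Col1a1 (0.01 and 0.11) and Pth1r (-0.20 and 0.04) did not pass on either day. The 21 adipocyte genes did not shift on day 2 (median 0.00, mean 0.01, camera direction down, adjusted p = 0.859) or day 5 (median -0.18, adjusted p = 0.413). The skeletal muscle list was lower in the arrays labelled knockout on day 2, with 17 of 21 genes negative (0 called, median -0.27, adjusted p = 4.91e-09, adjusted p = 0.0175 with an estimated correlation). The list mean on day 2 was 5.09, 5.51 and 5.01 on the arrays labelled knockout and 5.54, 5.54 and 5.38 on those labelled wild type, so replicate 2 of the knockout lay within the wild-type range. It was lower on day 5 too (median -0.26, adjusted p = 0.000614, adjusted p = 0.358 with an estimated correlation).

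On day 10, 5 genes differed, 4 of them lower in the arrays labelled knockout. Fabp4 was lower (5.58 ± 1.8 against 10.67 ± 1.8, n = 3 each, log2 difference -5.10, limma adjusted p = 0.00791). Its values were 4.02, 7.54 and 5.16 on the arrays labelled knockout, the first below its array's median, so the size of the difference is uncertain. The haemoglobin-binding protein gene Hp differed by -2.94 (adjusted p = 0.00746) and Dgat2, which encodes an enzyme of triglyceride synthesis, by -1.85 (adjusted p = 0.00746). The fetal skeletal myosin gene Myh8 was higher in the arrays labelled knockout (7.29 ± 0.70 against 4.27 ± 0.39, log2 difference 3.01, adjusted p = 0.0138), and all 3 wild-type values lay below their array's median, so the size of its difference is uncertain. The remaining gene, A530016L24Rik (-1.17, adjusted p = 0.0109), falls outside the naming rule and was chosen after its values were seen. All 21 adipocyte genes were lower in the arrays labelled knockout (median -1.40, camera adjusted p = 3.74e-29, adjusted p = 0.0238 with an estimated correlation), 2 past the test over all genes and 19 over the list alone. Without a whole preparation the estimated-correlation call held only without the third of the wild type (adjusted p = 7.36e-05, otherwise up to 0.243). All 13 early osteoblast genes were higher in the arrays labelled knockout (0 past the test, 0 over the list alone, median 0.51, adjusted p = 0.00558, adjusted p = 0.906 with an estimated correlation), with Msx2 (0.81) and Alpl (0.81) differing most. The list mean was 9.33, 8.83 and 9.42 on those arrays and 8.53, 8.78 and 8.93 on the wild-type arrays, so replicate 2 of the knockout lay within the wild-type range. Ibsp (1.48, adjusted p = 0.807) and Bglap (0.23) did not pass.

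The adipocyte list mean on day 10 was 8.45, 8.38 and 6.63 on the arrays labelled wild type and 5.64, 6.65 and 6.05 on those labelled knockout. The count of 5 genes fell to 0 without replicate 1 or 2 of the wild type, and to 3 without replicate 1 or 3 of the knockout. It rose to 54 without replicate 3 of the wild type and to 55 without replicate 2 of the knockout, the array with the most macrophage signal. Without replicate 1 of the wild type the adjusted p of Fabp4, Hp and Dgat2 was 0.0907 each, and without replicate 3 of the knockout that of Myh8 was 0.15.

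**Figure D4:**
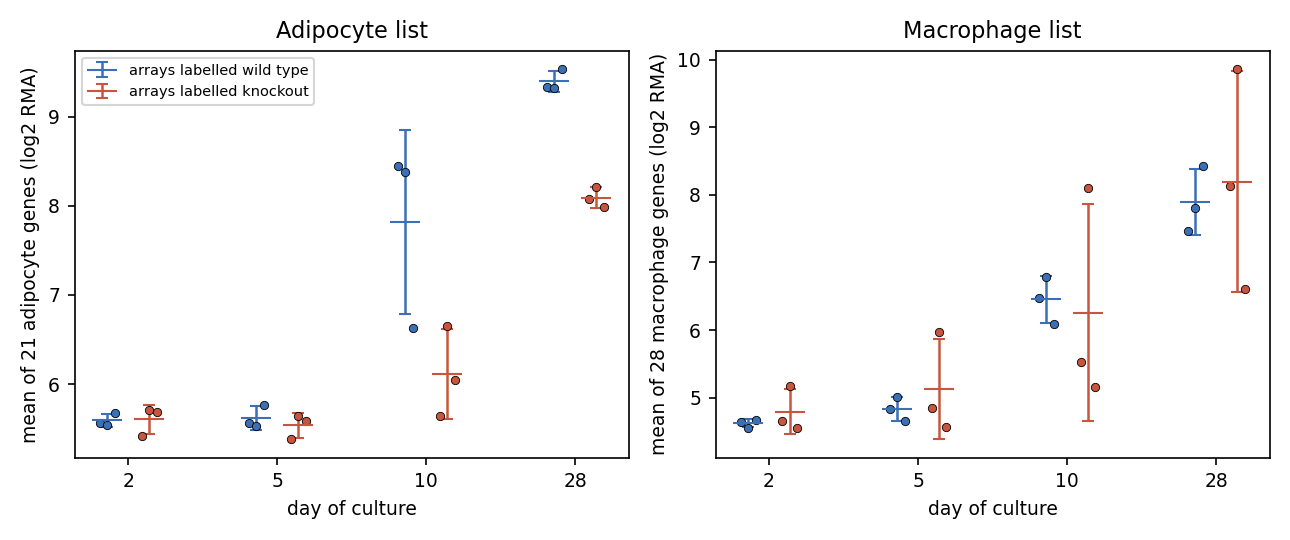
Mean log2 RMA value (vertical axis) of 21 adipocyte genes (left) and 28 macrophage genes (right) on every array by day of culture, with mean and SD of 3 arrays per group. On day 28 the adipocyte means are 9.32 to 9.53 in the arrays labelled wild type and 7.98 to 8.21 in those labelled knockout, and macrophage values spread from 6.60 to 9.86 in the latter.

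On day 28, 33 of 34 called genes were lower in the arrays labelled knockout, and 4 of the 33 belong to the adipocyte list. The largest difference among the called genes was that of the exception, Myh8, which was higher (2.68, adjusted p = 0.0206 in limma), but all 3 wild-type values lay below the array medians, so this size and rank are uncertain. Cox8b, a cytochrome oxidase subunit gene of brown fat and muscle, was 5.68-fold lower (5.17 ± 0.45 against 7.68 ± 0.71, n = 3 each, log2 difference -2.50, limma adjusted p = 0.00131). Lower too were Mrap, the melanocortin receptor accessory protein gene (-2.17, adjusted p = 0.0314), Tmem45b (-2.12, adjusted p = 0.000122), the lipogenic regulator Thrsp (-1.97, adjusted p = 0.00468) and Pck1 (-1.78). So were the FGF co-receptor gene Klb (-1.77, adjusted p = 0.0497), Rbp4 (-1.75), Chchd10 (-1.74), leptin (Lep, -1.71, adjusted p = 0.0301), Dgat2 (-1.69, adjusted p = 0.00539) and adipogenin (Adig, -1.65). Of the 34 genes 25 differed at least 2-fold. All 21 adipocyte genes were again lower (median -1.22, camera adjusted p = 8.4e-30, adjusted p = 0.0216 with an estimated correlation), 4 past the test over all genes and 17 over the list alone. With an estimated correlation that call was lost without any 1 knockout preparation (adjusted p = 0.114, 0.0732 and 0.128).

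The bone genes named here did not pass between the genotypes on day 28. Ibsp (1.63, adjusted p = 0.981), Dmp1 (1.28, adjusted p = 0.937), Alpl (0.74), Sp7 (0.86), Bglap (0.63), Sost (0.59), Pth1r (0.25) and Col1a1 (0.17) did not pass. All 13 early osteoblast genes were nonetheless positive (0 past the test, median 0.43, adjusted p = 0.000812, adjusted p = 0.74 with an estimated correlation), although the list mean of 8.43 on replicate 2 of the knockout was the lowest of the 6 arrays. Cholesterol synthesis (19 of 19 negative, 0 past the test, median -0.42, adjusted p = 8.6e-09, adjusted p = 0.74 with an estimated correlation) was lower in the arrays labelled knockout. Cell cycle (median -0.43, adjusted p = 5.34e-08, adjusted p = 0.806 with an estimated correlation) and oxidative phosphorylation genes (median -0.24, adjusted p = 5.34e-08, adjusted p = 0.74 with an estimated correlation) were lower as lists, with 0 genes past the test. The arrays of both lists overlapped between the genotypes. The cell cycle mean was 7.34, 7.86 and 6.49 on the arrays labelled wild type, the last the lowest of all 6, and 6.60, 7.13 and 6.70 on those labelled knockout. The oxidative phosphorylation mean was 8.96 on replicate 2 of the knockout against 8.91 to 9.11 in the wild type. Without single arrays the count of 34 ranged from 12 to 42, the lowest without replicate 2 of the wild type, 13 without replicate 3 and 22 without replicate 1 of the knockout, and 15 without replicate 1 of the wild type. Cox8b, Tmem45b and Thrsp kept their calls in all 6 of these fits. Klb lost its call in 6 of 6 (adjusted p up to 0.207), Lep in 5 (up to 0.17), Mrap, Adig, Pck1 and Myh8 in 4 (up to 0.202, 0.207, 0.127 and 0.134), Chchd10 and Rbp4 in 3 (up to 0.108 and 0.073) and Dgat2 in 1 (0.051, without replicate 2 of the wild type).

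Averaged over the 4 days, 28 genes differed, 4 higher and 24 lower in the arrays labelled knockout. Higher were Arrb2 (1.00), Tarbp1, which encodes an RNA methyltransferase (0.67, limma adjusted p = 0.0104), Abr (0.40, adjusted p = 0.021) and Myh8 (1.21, adjusted p = 0.0444). The Myh8 values of the wild type on days 10 and 28 and of the knockout on day 5 lay below the array medians. Myh8, named as a list member, was on average lower in the arrays labelled knockout on days 2 and 5, so its mean difference comes from days 10 and 28. Lower were Hp (-1.23, adjusted p = 0.0137), Ebf2, a transcription factor gene of adipocyte precursors (-1.01), Adhfe1 (-0.92), Trnp1 (-0.90, adjusted p = 0.000579), Dpep1 (-0.88), Cox8b (-0.83), Dgat2 (-0.80, adjusted p = 0.013), Nrn1 (-0.77) and Plac9a (-0.66). Dgat2, named as a list member, was on average higher in the arrays labelled knockout on day 5 (6.57, 6.55 and 6.11 against 5.83, 5.86 and 6.46). It was nearly level on day 2, so its mean difference comes from days 10 and 28. Trnp1 and Tarbp1 differed already on day 2 in size, though not past that day's test (Trnp1 6.30 ± 0.55 against 7.40 ± 0.42; Tarbp1 7.54 ± 0.04 against 6.99 ± 0.28). The adipocyte list was lower on average (median -0.70, 1 past the test and 19 over the list alone, camera adjusted p = 2.14e-27, adjusted p = 0.0312 with an estimated correlation). These p treat the 4 days of a preparation as independent, and the list was not tested with the preparation as the unit. Relative to the mean of all arrays of each day, the list lay at 0.50, 0.47 and 0.18 in the labelled wild-type preparations. In the labelled knockout preparations it lay at -0.59, -0.17 and -0.40. Treating the 4 arrays that share a replicate number within a genotype as 1 unit lowered the count. In all 3 genes remained with a random replicate block (Arrb2, Trnp1 and A530016L24Rik, the last outside the naming rule and chosen after its values were seen), and 0 with limma on the means of the 3 preparations per genotype. Without single arrays the count ranged from 11 to 74. Arrb2, Tarbp1, Trnp1, Hp and Dgat2 kept their calls in all 24 such fits. Abr lost its call in 4, Plac9a in 12, Nrn1 in 14, Ebf2 in 16, Cox8b in 17, Myh8 and Dpep1 in 19 and Adhfe1 in 20.

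Whether the change over time differed between genotypes was tested as a difference of changes. For days 5 and 10 limma called 0 genes (184 and 572 at an unadjusted p under 0.05), and for day 28 it called 1 gene, Tmem45b (410 at an unadjusted p under 0.05). These unadjusted counts also lie below what chance alone would give, so real differences may have been missed. Tmem45b, a transmembrane protein gene, went from 4.25 ± 0.22 to 7.13 ± 0.35 in the arrays labelled wild type and from 4.17 ± 0.06 to 5.01 ± 0.39 in those labelled knockout (difference of changes -2.04, adjusted p = 0.0428). All 6 day 2 values lay below the array medians, so the size of this difference is uncertain. It was the 1 gene of the F test over the days (adjusted p = 0.0401). Its call was lost in 9 of 12 fits without an array (adjusted p up to 0.217, without replicate 1 of the day 2 wild type). Both tests called 0 genes with the replicate block within genotype, and the day 28 test called 0 with no filter on dim genes (Tmem45b adjusted p = 0.0515). The adipocyte list changed less in the arrays labelled knockout by day 10 (median -1.21, 0 past the test and 12 over the list alone, camera adjusted p = 3.47e-23, adjusted p = 0.0495 with an estimated correlation). It did so by day 28 as well (median -1.34, 12 over the list alone, adjusted p = 8.68e-24, adjusted p = 0.0561 with an estimated correlation). Without replicate 3 of the day 10 wild type 27 genes were called for day 10, and 4 without replicate 2 of the day 10 knockout. The skeletal muscle list went the other way by day 10 (median 0.33, adjusted p = 3.52e-06, adjusted p = 0.0495 with an estimated correlation).

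A knockout allele can carry neighbouring DNA of another strain with it, so called genes were counted around Arrb2. Of the 200 nearest tested genes, 100 on each side, 3 were among the genes called over the mean of the days (Myh8, Abr and Trarg1), against 24 of 14596 other genes (Fisher's exact test, two-sided, odds ratio 9.24, p = 0.0056). Trarg1, an adipocyte trafficking gene, is outside the naming rule and was chosen after its values were seen. No called gene lay among the 50 nearest on each side (0, Fisher's exact p = 1), and with no filter on dim genes 1 of 200 did (exact p = 0.197). None of the 3 genes was called with the random replicate block or with the means of the preparations.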

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

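The tests of the Arrb2 labels, the test of windows of neighbouring genes, and the fits with sex-linked covariates and without a whole preparation were chosen after the result was seen. The count of calls near Arrb2 was planned, but its use to weigh chance was chosen after it was seen; the splits and the tests of list progress were not.

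Tmem45b had a smaller change by day 28 in the arrays labelled knockout (difference of changes -2.04, limma adjusted p = 0.0428), a call lost with the replicate block within genotype (0 genes called) and with no filter on dim genes (adjusted p = 0.0515). Its day 2 values lay below the array medians, so the size of the difference is uncertain. Gene lists whose change from day 2 differed between the genotypes, by camera with the preset correlation, were as follows, each as the median of the labelled knockout minus the labelled wild type. For day 5 these were the inflammatory (-0.25) and cholesterol synthesis lists (-0.26), both at adjusted p = 0.991 with an estimated correlation. For day 10 they were early osteoblast (0.47), cell cycle (0.34), smooth muscle (0.25) and oxidative phosphorylation genes (-0.20), each at adjusted p = 0.996 with an estimated correlation, the IGF axis (-0.32, adjusted p = 0.774 with an estimated correlation), and the adipocyte (-1.21) and skeletal muscle lists (0.33), both at adjusted p = 0.0495 with an estimated correlation. For day 28 they were early osteoblast (0.46, adjusted p = 0.696 with an estimated correlation), cell cycle (-0.37, adjusted p = 0.884), adipocyte (-1.34, adjusted p = 0.0561), skeletal muscle (0.15, adjusted p = 0.446), and smooth muscle (0.29), oxidative phosphorylation (-0.26) and cholesterol genes (-0.58), the last 3 at adjusted p = 0.688 with an estimated correlation.

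Transcript clusters without a single gene name, which enter no comparison above, also differed between the genotypes: of 8177 tested, 3 were called on day 2, 3 on day 5, 3 on day 10, 4 on day 28 and 13 over the mean of the days. Cluster 17549150 was higher in the arrays labelled knockout by 4.67, 3.44, 3.47 and 3.12 on days 2, 5, 10 and 28 and cluster 17549062 by 4.33, 3.41, 3.03 and 2.91, while cluster 17419031 differed by -2.22, -2.71, -2.32 and -2.56. They were chosen after their values were seen. Of the 13 clusters, 7 list several genes.

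Arrb2 was higher in the arrays labelled knockout. Single mislabelled arrays are argued against for days 2, 5 and 10, where 9 of 9 arrays labelled knockout lay above every array labelled wild type of their day. On day 28 1 of 3 did, so Arrb2 does not decide there. The 3 clusters called on days 2, 5 and 10 do argue against a single wrong label on day 28. Labelled knockout and wild type were at 8.25 ± 0.37 and 5.34 ± 0.30 for 17549062 and at 8.42 ± 0.24 and 5.31 ± 0.37 for 17549150. For 17419031 they were at 5.38 ± 0.47 and 7.94 ± 0.33. All 3 arrays labelled knockout lay outside the wild-type range each time. An exchange of all genotype labels stays open: the lowest Arrb2 value among the arrays labelled wild type lay 0.39 above its array's median, which decides only if the probes lie in the deleted part, and that is not known here. A change of the remaining transcript in true knockout cells was not tested and stays open as well.

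Calls over the mean of the days lay near Arrb2 more often than elsewhere (Myh8, Abr and Trarg1) in the fit without a replicate block. None of the 3 was called with the random replicate block or with preparation means, so the pattern rests on treating the days of a preparation as independent. Whether a stretch of DNA around Arrb2 that differs between the genotypes contributes is not settled. The 200 tested genes around Arrb2 had a mean absolute statistic (1.22) above 99.2% of 120 such windows, in the same fit without a block. These windows overlap, so they are not independent comparisons. Among the 50 nearest tested genes on each side 0 were called. With no filter on dim genes 1 of 200 was (Fisher's exact p = 0.197). Myh8 was on average lower in the arrays labelled knockout on days 2 and 5, while Abr was on average higher on each day. A grouping of few calls by chance stays open, since Fisher's exact p of 0.0056 rests on 3 calls and was 0.0355 with 200 genes on each side and 0.0478 without Trarg1. No biological explanation was tested.

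Adipocyte genes were lower in the arrays labelled knockout on days 10 and 28. With Xist and Y-linked covariates the day 28 median was -1.41. In that fit the camera call with an estimated correlation was lost (adjusted p = 0.101 on day 10 and 0.139 on day 28). The covariates share 1 slope over all days and cannot remove a sex effect limited to late days, so unequal sex makeup stays open. A single preparation, by replicate number, is argued against as the sole source by medians of -1.17 or lower without any of the 6. Of 10000 random lists matched on the wild-type change at the other of these days, 0% had as low a median on either day. Without the extreme tails, their medians lay from -0.62 to -0.05 on day 10 and from -0.27 to 0.12 on day 28. The matched genes were thus lower too on day 10 (median -0.34), though less so than the adipocyte list. The random lists drew genes independently, while adipocyte genes move together, so slower overall progress of the knockout cultures is not excluded. An effect of the genotype on fat cell differentiation remains a hypothesis, as does a different share of adipocyte precursors in the 3 preparations of each genotype, which was not tested, and the direction rests on labels that Arrb2 goes against.

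The 10 splits of 6 arrays are too few for a share under 0.05. Against day 2 the real split called 826, 4568 and 5774 genes in the labelled wild type (highest other 1, 1 and 0) and 412, 3665 and 5658 in the labelled knockout (highest other 14, 0 and 0), the real split alone (1 of 10) giving as many each time. Between genotypes the values were 1 on day 2 (highest other 1; 2 of 10 splits as large), 1 on day 5 (highest other 1; 3 of 10), 5 on day 10 (highest other 4; 1 of 10) and 34 on day 28 (highest other 309; 2 of 10). The adipocyte medians were 1.40 in size on day 10 (highest other 1.16) and 1.22 on day 28 (highest other 0.58). The split with 309 genes set replicates 1 and 2 of the wild type with replicate 2 of the knockout, which points to a structure of the samples. For the mean over days, 2 of 100 relabellings within days gave as many as 28 genes (highest other 127). Such relabelling parts the arrays that share a replicate number. Their deviations correlated past the pairing limit within a genotype, except for days 10 and 28 of the wild type. Exchange of whole preparations gave 4 of 10 splits as large, up to 1248 genes, and preparation means called 0, so the preparations differ in a structure of their own and chance in their grouping is not excluded. For the differences of changes on day 28 and on any day chance cannot be excluded, since 16 and 26 of 100 relabellings gave as many genes (1 gene each; highest other 48 and 268). For days 5 and 10 the real count was 0, so that 100 of 100 relabellings gave as many by construction and decide nothing (highest other 6 and 2).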

How the results depend on the processing

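Leaving out whole preparations, the Xist and Y-linked covariates, preparation means and the neighbourhood without Trarg1 were chosen after the data were seen; the other alternatives were not. Of 658 results of named genes past the threshold, 157 lost the call in at least 1 of the fits compared (216 of 5217 fits) and 0 reversed. For each result these fits were alternatives that kept all arrays, and the fits without 1 array that gave the lowest and the highest change. The cause of the following changes was not tested, except that fits of only the 2 groups compared hold fewer arrays. Genes changed by day 5 numbered 1366 with the replicate block within genotype and 463 from only the 2 groups in the labelled wild type. In the labelled knockout they numbered 911 with array weights, 620 with the shared-number replicate block, 695 with the replicate block within genotype and 49 from only the 2 groups. Between genotypes, array weights gave 4, 38, 96 and 104 genes (days 2, 10, 28 and mean over days), the shared-number replicate block 2, 31 and 51 (days 2, 10 and mean), only the 2 groups 0, 1 and 22 (days 2, 10 and 28), and the sex-linked covariates 0 and 11 (day 2 and mean). No filter on dim genes gave 2 on day 5, a stricter filter 18 on day 28, the random replicate block 3 and preparation means 0 for the mean over days. The day 28 interaction gave 0 genes with no filter, 4 with array weights and 0 with the replicate block within genotype. The interaction on any day gave 2 with a stricter filter, cyclic loess or the trended robust prior, 4 with array weights and 0 with the replicate block within genotype. With an estimated correlation, the lists called numbered 2, 0 and 0 (labelled wild type, days 5, 10 and 28), 2, 0 and 0 (labelled knockout), 0, 1, 1 and 1 (genotypes, days 5, 10, 28 and mean) and 0, 2 and 0 (interactions, days 5, 10 and 28). With fry they were 4 and 20 (labelled wild type, days 5 and 28), 2 (labelled knockout, day 5), 0, 0, 1, 1 and 1 (genotypes, days 2, 5, 10, 28 and mean) and 0, 0 and 0 (interactions). The shared-number replicate block gave 10 lists on day 28 between genotypes, and no filter gave 1 for the day 5 interaction. Without a filter the changes of the genotypes correlated at 0.721, 0.861 and 0.922. Among 50 genes on each side of Arrb2 the odds ratio was 0 (Fisher's exact p = 1), and 4.75 with no filter (exact p = 0.197). Among lists not described with the comparisons, the replicate block within genotype brought the complement list past the threshold on day 5 in the labelled wild type (adjusted p = 0.1 to 0.0393, but adjusted p = 0.432 with an estimated correlation and the block). In the labelled knockout on day 5 it ended the calls of the Notch and Hedgehog (0.0634), skeletal muscle (0.0574) and glycolysis lists (0.0574). Among genes not described with those comparisons, it brought past the threshold Cd53 (0.00529), Serping1 (0.0149), Uty (0.0333) and Cd55 (0.0337) and ended the call of Epyc (0.0558) on day 5 in the labelled wild type. In the labelled knockout it brought past Acan (0.00272), Acp5 (0.0141) and Tubb3 (0.0418) on day 5 and Tek (0.0256) on day 10. It changed no other call of a list, or of a gene the naming rule takes, in the paired comparisons beyond those given with them. For the unpaired comparisons 5 and 6 of 6 arrays correlated best with their own number (wild type, days 10 and 28), and 4, 2, 4 and 4 between genotypes (days 2, 5, 10 and 28).

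Without single arrays the counts ranged from 355 to 1067, 3554 to 4175 and 4788 to 5264 in the labelled wild type, and from 124 to 408, 2396 to 3193 and 4514 to 5094 in the labelled knockout (days 5, 10 and 28). Between genotypes they ranged from 0 to 2, 1 to 1, 0 to 55, 12 to 42 and 11 to 74 (days 2, 5, 10, 28 and mean), and for the interactions from 0 to 0, 0 to 27, 0 to 3 and 0 to 35 (days 5, 10, 28 and any). Day 2 fell to 0 without any replicate of the wild type or replicate 2 of the knockout and rose to 2 without replicate 1 of the knockout. The mean over days reached 74 without replicate 3 of the day 10 wild type and 56 without replicate 2 of the day 10 knockout, and fell without replicate 1 or 3 of the day 2 wild type (16 and 13), 2 or 3 of day 5 (17 and 11), 1 or 2 of day 10 (18 each) and 1 of day 28 (16). It fell likewise without replicate 1 or 3 of the day 2 knockout (15 and 18), 1 or 2 of day 5 (12 and 18), 1 or 3 of day 10 (18 each) and 1 or 3 of day 28 (15 and 18). The interaction on any day reached 35 without replicate 3 of the day 10 wild type. Without whole preparations the ranges were 0 to 1, 1 to 1, 0 to 79, 9 to 52 and 3 to 149 genes, and the adipocyte medians -1.82 to -1.20 on day 10 and -1.36 to -1.17 on day 28. With an estimated correlation the day 10 adipocyte shift passed without the third wild-type preparation (adjusted p = 7.36e-05) and was lost without any other (0.149 and 0.243 for the first and second of the wild type, 0.118, 0.082 and 0.126 for those of the knockout). The day 28 shift was lost without each knockout preparation (0.114, 0.0732 and 0.128). With the sex-linked covariates these p were 0.101 and 0.139, and with the shared-number replicate block 0.0651 and 0.0597. Dim probes limit what can be seen near the background, and the number of arrays limits the rest.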

Other observations

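No test was chosen for this part after the result was seen. Smooth muscle and myofibroblast genes were lower on day 28, 12 of 18 in each genotype and 1 higher (13 and 14 over the list alone, medians -0.98 and -0.81, camera adjusted p = 7.86e-05 and 0.00285, adjusted p = 0.367 and 0.389 with an estimated correlation), with Cnn1 at -2.77 and Tagln at -2.32 in the labelled wild type. Of 15 osteoclast genes 5 rose and 1 fell by day 28 in the labelled wild type (6 over the list alone, median 0.30, adjusted p = 0.0918), with the proton pump subunit gene Atp6v0d2 at 4.03 (from day 2 values below the array medians), the tartrate-resistant phosphatase gene Acp5 at 2.20 and the transcription factor gene Nfatc1 at -1.28. In the labelled knockout 6 rose (7 over the list alone, median 0.39, adjusted p = 0.0136, adjusted p = 0.337 with an estimated correlation). Matrix protease genes rose in 10 of 18 cases and 1 fell by day 28 in the labelled wild type (11 over the list alone, median 0.80, adjusted p = 0.00385, adjusted p = 0.367 with an estimated correlation). Glycolysis and hypoxia genes went down by day 10 in the labelled wild type, 11 of 23 lower and 2 higher (15 over the list alone, median -0.63, adjusted p = 0.00575, adjusted p = 0.424 with an estimated correlation), among them the lactate transporter gene Slc16a3 (-2.04), Vegfa (-1.91), Hk2 (-1.66) and the glucose transporter gene Slc2a1 (-1.59).

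The preparations differed in make-up. Xist was at 3.56 to 4.31 on the arrays of replicate 2 of the labelled wild type and at 7.72 to 10.02 on the others. The Y-linked gene Eif2s3y was at 3.46 to 3.80 on replicate 3 of the labelled wild type on days 2, 10 and 28 and at 5.94 on day 5, and at 4.71 to 8.32 on the arrays of the other preparations. Relative to the means of all arrays of each day, both genotypes together, replicate 2 of the labelled knockout lay 1.25 higher in the macrophage list and 0.75 higher in the interferon list, and replicate 3 lay lower (-0.81 and -0.49).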
